A study of Mus musculus with 150 samples.

How the data were processed

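The series holds 150 single-channel Illumina bead arrays of total RNA from heart, liver, muscle and fat of male C57BL/6NIA mice, a substrain of the C57BL/6 laboratory mouse. RNA was amplified and labelled with biotin, per the labels' protocols. The submitters' processing notes name BeadStudio version 1, the array maker's software. Each array carries the code of an animal and of its diet group. Arrays were grouped by the labels into 10 diet groups in each of the 4 tissues. The labels give an age of 11 months for every array, although the diets began later, so they do not state the age at which tissue was taken.

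The score values, as deposited, had already been normalized to z-scores within each array; this is read from the values, with a mean near 0 and an SD near 1 on every array, and the processing notes used here do not state it. In the files the array means ran from -0.00699 to 0.0179 and the SDs from 0.997 to 1.02. The log base and the scale of the signal under the z-scores are not given in the sources used here, so differences are stated in z-score units and never as fold changes. A difference of 1 unit is 1 SD of all probe values on an array. No raw intensity, detection p-value, slide or scan date was used here, so array batches could not be modelled. Of 24600 rows, 19025 held a value in at least 1 tissue and 13019 in all of them. Heart and fat had values for 14849 probes, and liver and muscle for 17195.

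Because the values were already normalized, they were used as deposited, where the plan had assumed log2 values. Probes whose mean over a tissue lay below its 40th percentile were left out, which kept 8909 probes in heart and fat and 10317 in liver and muscle. For each tissue a linear model with 1 mean per group was fitted to all of its arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). P-values were adjusted by the Benjamini-Hochberg method over the probes of a comparison, and a probe passed at an adjusted p below 0.05. All tests were two-sided. The 2 resveratrol doses were averaged with equal weight in each resveratrol comparison, and the dose difference was tested separately. Differences of effects between heart, liver and muscle were tested with a moderated F test on 2 degrees of freedom over 6273 probes kept in all 3 tissues. Fat was left out of that test because most of its groups had 2 arrays. Correlations of effects were taken across probes, which are not independent replicates, and were set beside 100 simulations in which residuals of the same arrays were dealt at random to groups of the same sizes.

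The files identify probes by Illumina IDs alone. The gene table at hand (GRCm38.p6) lists 0 of these IDs, so no probe could be given a gene name. The 31 pathway lists and 15 cell type lists fixed in the plan, the rule of 1 probe per gene, the mean over a gene's probes and the planned values of Sirt1 and Ppargc1a could therefore not be used. The rule for named items took the largest rise and the largest fall among the probes that passed. Without gene names it was narrowed to 4 liver probes, a choice made after the values were seen, and probes past the threshold were otherwise counted by direction.

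The fit was tested on simulated values drawn from the real probe means and SDs with the real group sizes, in which 200 probes of the high-calorie group were shifted. Of 100 probes shifted by 0.5 units, 96 were recovered in heart and 87 in liver (8909 and 10317 probes), 95 in muscle (10317 probes) and 68 in fat (8909 probes). Of 100 probes shifted by 1 unit, 99 were recovered in heart, 100 in liver, 99 in muscle and 95 in fat. Between 1 and 13 unchanged probes were called. The simulated probes varied independently of each other, so false calls from variation shared by probes were not tested. In the same test of the difference by tissue, 196 of 200 probes shifted by 1 unit in liver were recovered among 6273, with 9 false calls. A shared variance of 0.04 put into 2 effects in heart came back as 0.0412 over 8909 probes. For this the known noise of the shared control was subtracted, so the comparison with dealt residuals used for the real correlations was not checked.

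The alternatives set before the data were examined were no filter on dim probes, quantile normalization in place of the z-scores, a fit of the compared groups alone, each array left out in turn, the group SD27 as the control in place of SD18, the animal code as a random block for the tissue differences (its correlation estimated on 2000 probes), and shared controls divided between the comparisons for the correlations. Alternatives added after the data were seen were SD27 as the control for further results and the liver alternate-day comparisons without 2 arrays. The number of arrays limits the precision. All arrays were used, including 3 marked RPT in the labels and a fat array made from RNA of a pair of animals. That animals were separate is read from their codes. P-values measure the spread between these arrays.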

Results

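Gene expression was measured in heart (43 arrays), liver (40 arrays), muscle (45 arrays) and fat (22 arrays) of male mice in 10 groups, set by diet and, for the standard diet alone, by a number in the label. The standard diet was AIN-93G, a purified rodent diet. Resveratrol, a plant polyphenol, was added at 0.01% or 0.04% of the diet (groups SDLR and SDHR). Further mice ate the standard diet on alternate days with 24 h without food in between (EOD), alone or with the same doses (EODLR and EODHR). The high-calorie diet contained hydrogenated coconut oil to give 60% of calories from fat and began 6 weeks later than the others (HC, HCLR and HCHR). Mice on the standard diet alone formed a pair of groups, SD18 and SD27, whose numbers carry no unit in the labels. Groups held 3 to 5 arrays in heart, liver and muscle, and 2 or 3 in fat. Arrays of a tissue were alike, with pairwise correlations from 0.823 to 0.996 over all probes, and no pair held identical values.

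In every tissue the arrays fell into 2 sets. The groups SD18, HC, HCLR and HCHR lay on the negative side of the first principal component, and SD27, SDLR, SDHR, EOD, EODLR and EODHR lay on the other side. This component held 62.9% of the variance in heart, 30.1% in liver, 21.5% in muscle and 68.3% in fat. In heart the first set ran from -0.228 to -0.128 and the second from 0.0871 to 0.164. The gap was narrower in the other tissues. The first set ended and the second began at -0.0731 and 0.00369 in liver, -0.0412 and 0.0124 in muscle, and -0.0729 and 0.0202 in fat. No group had arrays on both sides in any tissue, so for a comparison that crosses the sets, set membership and diet cannot be told apart. The comparisons of SD27, EOD, SDLR and SDHR with SD18 cross the sets. The comparison of HC with SD18, those of resveratrol with its own HC or EOD group, and those of EOD, SDLR and SDHR with SD27 stay within a set. For the counts of EOD, SDLR and SDHR that cross, the count within a set is given beside it; that of SD27 with SD18 has none.

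**Figure D1:**
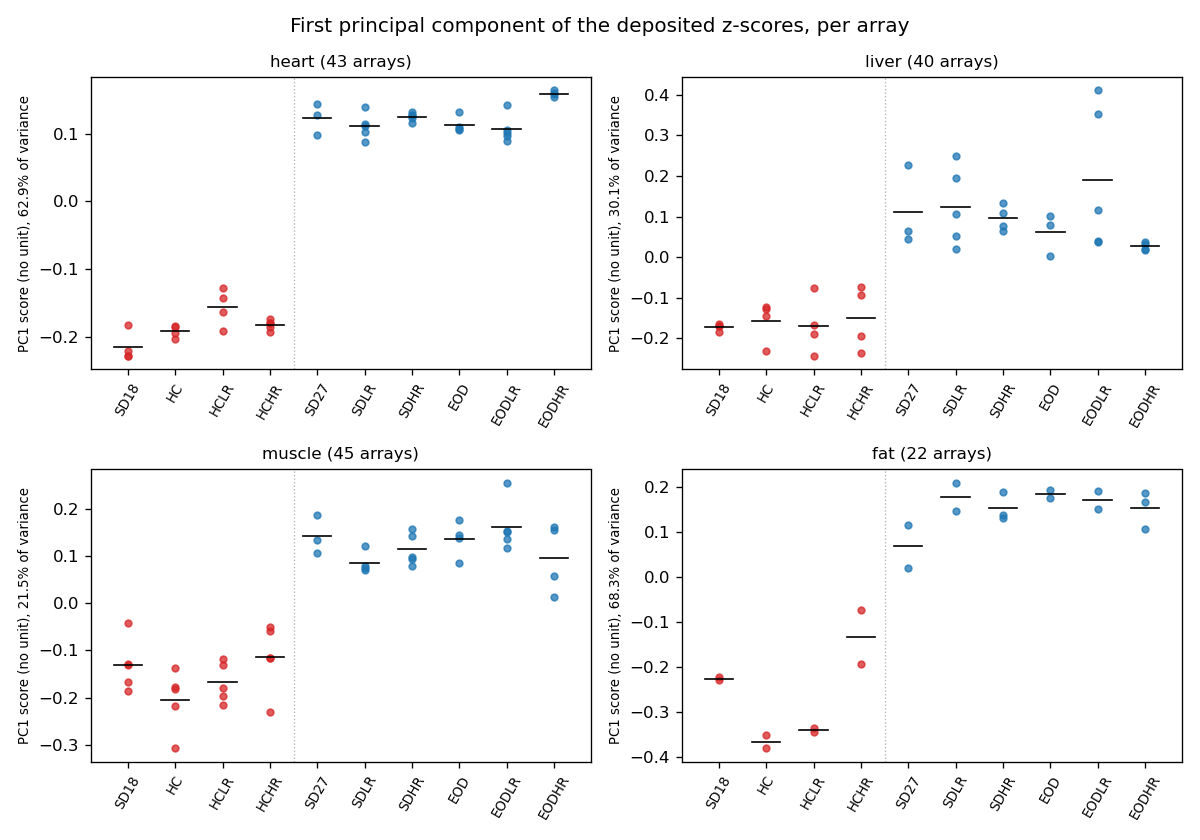
Score of each array (points) on the first principal component of the deposited z-scores (vertical axis, no unit) by diet group (horizontal axis), with the group mean as a bar, in each tissue. SD18 and the high-calorie groups (red) do not overlap with the other groups (blue) in any tissue. The red set ends and the blue set begins at -0.128 and 0.0871 in heart. These edges lie closer together at -0.0731 and 0.00369 in liver, -0.0412 and 0.0124 in muscle, and -0.0729 and 0.0202 in fat.

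The high-calorie diet against the standard diet (HC against SD18) asks what the fat-rich diet changed. Most probes passed in fat, with 2 arrays in each group: 1221 rose and 1378 fell among 8909. Calls among dim probes were also most frequent there. Of 1458 probes among the dimmest 30% in every tissue, 8.50% passed in fat, 0.960% in liver, 0.274% in muscle and 0% in heart. In liver 197 rose and 302 fell among 10317. In muscle 129 rose and 98 fell, and in heart 10 rose and 17 fell. The median size of the change among these probes was 0.427 z-score units in fat, 0.352 in liver, 0.246 in muscle and 0.384 in heart, against a median 95% half-width of 0.197, 0.153, 0.136 and 0.144 units. Probes that passed in muscle and fat shared direction more often than independent lists would: 25 rose in both against 10.8, 21 fell in both against 9.72, and 3 moved in opposite directions. In liver and fat 53 fell in both against 34.1, 15 rose in both against 17.4, and 35 moved in opposite directions. The balance of directions changed with the processing: the compared groups alone gave 380 higher and 265 lower probes in liver and 550 and 343 in fat, no filter gave 1388 and 1385 in fat, and quantile normalization gave 145 and 150 in muscle. These counts depended on single arrays. In heart 7 probes passed without SD18 1E, 14 without SD18 1F and 8 without HC 7D. In liver 277, 268 and 331 passed without SD18 1D, 1F and 1G, and 314 and 329 without HC 7A and 7C. In muscle 92 and 112 passed without SD18 1F and 1H, 121, 101 and 111 without HC 7A, 7B and 7E, and 356 without HC 7D. In fat 1690 passed without SD18 1G and 1213 without HC 7D, and the fit of the compared fat groups alone gave 893.

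The largest rise on the high-calorie diet in liver was that of probe ILMN_2617625, from 0.00959 ± 0.510 (SD, n = 4) in SD18 to 2.89 ± 0.267 (SD, n = 4) in HC. The difference was 2.88 units with an SE of 0.549 and an adjusted p of 0.00176 (limma). With resveratrol its mean on the high-calorie diet was 1.40 ± 1.09 (SD, n = 4) at 0.01% and 0.839 ± 1.07 (SD, n = 4) at 0.04%. The largest fall was that of ILMN_1234449, from 3.69 ± 0.210 (SD, n = 4) in SD18 to -0.543 ± 0.0620 (SD, n = 4) in HC. Its difference was -4.23 units with an SE of 0.812 and an adjusted p of 0.00187 (limma). The HC values of this probe lay below the lowest median of a liver array, -0.437. Signal over background is not known, so the size of the fall is uncertain. The mean of ILMN_1234449 was 1.80 ± 1.64 (SD, n = 4) in HCLR and 2.51 ± 1.12 (SD, n = 4) in HCHR, and -0.316 ± 0.401 (SD, n = 3) in EOD. Neither probe passed for resveratrol on the high-calorie diet against HC, both doses averaged. Both were picked for their difference between HC and SD18, so the means in HCLR and HCHR do not show a reversal by resveratrol. The HC and SD18 arrays did not overlap for either probe. SD27, in the other set, was at 2.22 ± 2.52 (SD, n = 3) for ILMN_1234449, and its lowest array, 1B at -0.690, lay under the HC arrays (-0.589 to -0.453). Against SD27 the differences were -2.76 units for ILMN_1234449 and 2.36 for ILMN_2617625.

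**Figure D2:**
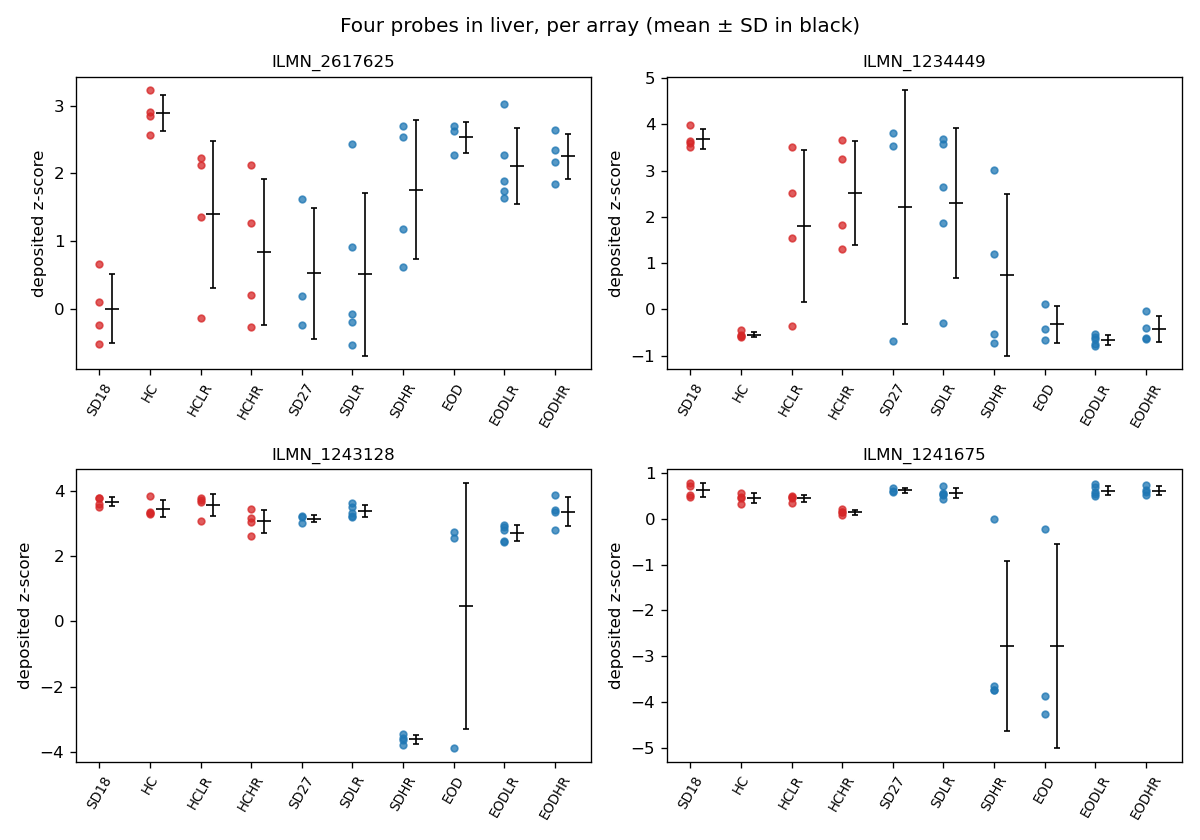
Deposited z-scores (vertical axis) of 4 liver probes in each array (points), by diet group (horizontal axis), with the group mean and SD in black. ILMN_2617625 is high and ILMN_1234449 low in HC against SD18; ILMN_1243128 and ILMN_1241675 each lie below -3 in 5 arrays of SDHR and EOD.

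Resveratrol on the high-calorie diet was compared with that diet alone, both doses averaged. In fat 656 probes rose and 1248 fell. In muscle 215 rose and 34 fell, and in liver 14 rose and 25 fell. In heart no probe passed in limma, and 470 had an unadjusted p below 0.05, where 445 would by chance. In muscle 711 probes rose and 167 fell in HCHR against HC, and none passed in HCLR, where 767 had an unadjusted p below 0.05. The excess of rises in muscle was smaller without the filter, at 733 and 462 for 0.04% and 228 and 139 for both doses, and after quantile normalization, at 483 and 192 for 0.04%. Of the 1458 dimmest probes 4.94% passed at 0.04% in muscle, 14 higher and 58 lower. In fat 1319 rose and 2367 fell at 0.04%, and 1 rose and 2 fell at 0.01%. At 0.04% in fat the compared groups alone gave 545 higher and 821 lower probes, and 34.6% of the same 1458 probes, those among the dimmest 30% in every tissue, passed. The difference between doses itself passed for 882 higher and 1663 lower probes in fat and for 96 higher and 11 lower probes in muscle; in the fit of the compared groups alone it passed for 46 in fat and 5 in muscle. Without the filter on dim probes the balance in fat turned, to 3310 higher and 2679 lower at 0.04%, 2549 higher and 1844 lower between doses, and 1546 higher and 1435 lower for both doses. It passed for no probe in heart (597 at an unadjusted p below 0.05) or liver (340) in limma. Among probes tested in both tissues, 284 that passed at 0.04% moved in opposite directions in muscle and fat, where independent lists would give 154, while 12 rose in both and 6 fell in both.

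Within a tissue, probes that passed for the diet and for resveratrol on it mostly moved in opposite directions. In fat 588 that rose on the diet fell with resveratrol and 198 that fell on the diet rose with it, against 171 and 101 for independent lists, and 34 moved the same way. In muscle 36 that fell on the diet rose with resveratrol against 2.04, and 3 that rose fell against 0.425. In liver 20 that rose fell against 0.477, and 6 that fell rose against 0.410. Both comparisons use the HC arrays, with opposite sign, which adds such overlap without any effect. Across probes the correlation of the 2 effects was -0.148 in heart, -0.679 in liver, -0.554 in muscle and -0.565 in fat, where simulations without any effect gave medians of -0.578, -0.567, -0.614 and -0.559. The covariance was -0.0174 in liver against a simulated -0.00592 (95% of simulations between -0.0136 and -0.00149). In fat it was -0.0582 against -0.00854 (-0.0208 to -0.00033). In muscle it was -0.00754 against -0.00368 (-0.00761 to -0.00134), within the simulated range, and in heart -0.00115 against -0.00347 (-0.00620 to -0.00174). With the HC arrays split between the comparisons the covariance was -0.0130 in liver, -0.00384 in muscle, 0.00142 in heart and, with 1 HC array in each comparison, -0.0469 in fat.

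The counts for resveratrol on the high-calorie diet moved with single arrays. In heart 1 probe passed without HC 7D, and the doses differed for 33 probes without HCLR 8D. At 0.01% in fat 0, 273, 32 and 34 passed without HC 7D, HC 7E, HCLR 8C and HCLR 8D, and in muscle 2 without HC 7E and 1 without HCLR 8C. In fat 256 probes passed without HC 7D and 1202 without HCHR 9D, and the compared groups alone gave 28. At 0.04% in fat 2127 passed without HC 7D and 2060 without HCHR 9D. The fat dose difference fell to 1061 without HCLR 8D and 815 without HCHR 9D, and under quantile normalization it passed for 611 higher and 684 lower probes. The fat comparison at 0.04% then had 1364 higher and 1541 lower probes. In muscle 47, 158, 116 and 153 probes passed without HC 7B, 7A, 7C and 7D, 503 without HC 7E, and 160 and 143 without HCLR 8D and 8E. Quantile normalization gave 157 higher and 50 lower probes there. At 0.04% in muscle 470 passed without HC 7B and 539 without HCHR 9B. The muscle dose difference fell to 2 without HCLR 8B or HCHR 9B, 3 without HCHR 9D, 39 without HCHR 9A, 47 without HCLR 8C, 55 without HCLR 8A and 63 without HCHR 9C, and rose to 233 without HCHR 9E. In liver the count lay between 1, without HC 7A, and 76, without HCLR 8C, and moved by over 1.5 times without 9 of the 12 arrays.

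Alternate-day feeding was compared with the standard diet. Against SD18, which crosses the sets, 2780 probes rose and 3000 fell in heart, 701 and 1213 in liver, 1061 and 837 in muscle, and 1910 and 2883 in fat. Against SD27, within a set, 176 rose and 342 fell in heart, 694 and 674 in liver, 14 and 45 in muscle, and 59 and 234 in fat. In heart 2 of the 35 splits of the EOD and SD27 arrays, the real one included, gave as many probes (highest other 765), so chance was not excluded for that count. Staying within a set did not free the liver comparison of calls among dim probes. Of 1458 probes among the dimmest 30% in every tissue, 8.44% passed against SD27 (117 higher and 6 lower) and 1.85% against SD18. In heart 0.754% passed against SD27, in muscle 0.0686% and in fat 0.549%. Probes that passed against both controls numbered 344 in heart, 562 in liver, 26 in muscle and 236 in fat. Of these, 243, 560, 26 and 229 had the same direction, and any others had opposite directions. Both comparisons use the EOD arrays, which adds such overlap, and no value for independent lists was computed. The median change among probes that passed against SD27 was 0.299 units in heart, 0.298 in liver, 0.405 in muscle and 0.519 in fat. Heart and liver shared 21 rising probes against 8.43 for independent lists and 58 falling probes against 21.5 in that comparison, with 5 in opposite directions. The counts against SD27 ran from 149 without SD27 1B to 832 without EOD 4B in heart, from 389 without EOD 4C to 1435 without SD27 1C in liver, from 20 without EOD 4C to 56 without SD27 1C in muscle, and from 2 without EOD 4D to 618 without SD27 1A in fat. Against SD18 the liver count was 1131 without EOD 4C. Quantile normalization gave 967 higher and 1189 lower probes in muscle against SD18, and no filter 2955 and 4721 in heart and 3706 and 3239 in fat. The compared groups alone gave 981 and 1094 in liver.

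**Figure D3:**
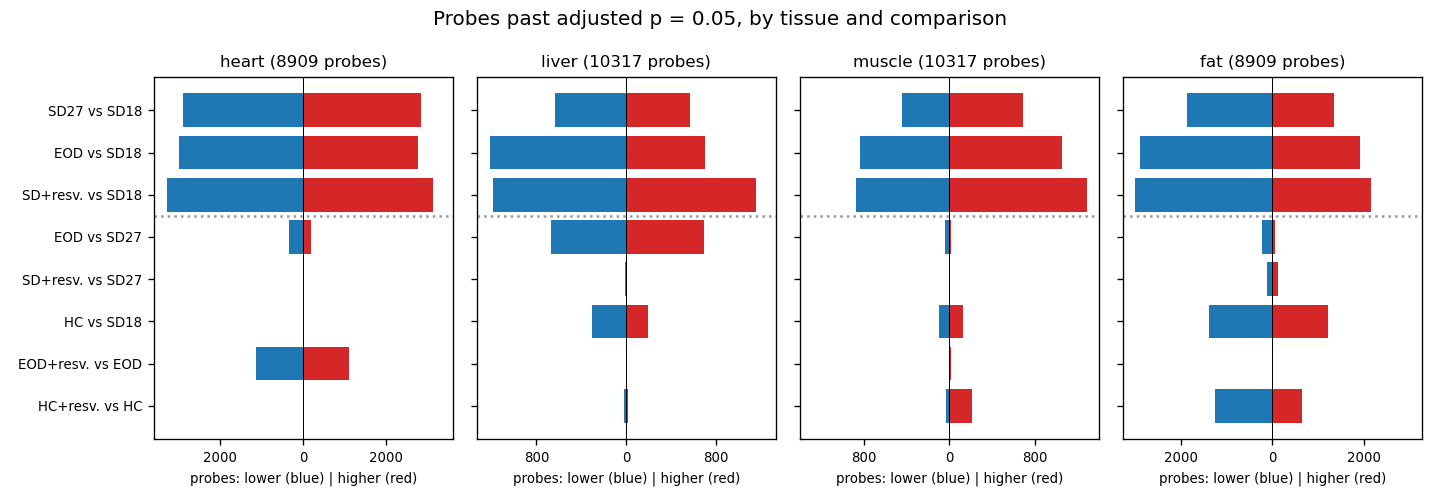
Number of probes (horizontal axis) with an adjusted p below 0.05 that were higher (red, right) or lower (blue, left) in each comparison (vertical axis), by tissue; the axes of the tissues differ in range. Comparisons above the dotted line cross the sets of arrays seen in the principal component, and those below it stay within a set: in heart, resveratrol on the standard diet gave 3122 higher and 3289 lower probes against SD18 and none against SD27.

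Resveratrol on the standard diet was compared in the same way. Against SD18, 3122 probes rose and 3289 fell in heart, 1158 and 1183 in liver, 1296 and 872 in muscle, and 2146 and 3004 in fat. Against SD27, no probe passed in heart in limma, where 317 had an unadjusted p below 0.05 and 445 would by chance. In liver 4 rose and 12 fell, in muscle 1 fell, and in fat 115 rose and 121 fell. The median 95% half-width of a difference against SD27 was 0.134 units in heart, 0.144 in liver, 0.144 in muscle and 0.166 in fat. The counts against SD27 ran from 0 without SD27 1A to 7 without SD27 1B in heart, to 55 without SDLR 2A in liver and to 8 without SD27 1B in muscle, and in fat from 14 without SDLR 2D to 580 without SD27 1A. The doses differed in liver, where 471 probes were higher and 51 lower at 0.04% than at 0.01%. That liver count was 293, 300 and 255 without SDHR 3A, 3B and 3E. No probe passed between doses in heart (563 at an unadjusted p below 0.05), muscle (156) or fat (311) in limma; 3 did in heart without SDHR 3B or 3E, and 1 in fat without SDLR 2A. Quantile normalization gave 1094 higher and 1216 lower probes in muscle against SD18, and no filter 1267 and 1269. Without the filter 3305 rose and 5963 fell in heart and 3664 and 3387 in fat, and in liver the compared groups alone gave 1333 and 1222.

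Probe ILMN_1243128 fell in liver by -3.78 units against SD18 (adjusted p 1.66e-05, limma) and by -3.26 against SD27 (adjusted p 0.0273, limma). The size of this fall is not well defined, since it rests on SDHR values below every value of the probes other than ILMN_1241675, and it was -2.74 units against SD18 after quantile normalization. Its mean was 3.67 ± 0.134 (SD, n = 4) in SD18, 3.14 ± 0.107 (SD, n = 3) in SD27 and 3.38 ± 0.186 (SD, n = 5) in SDLR, but -3.61 ± 0.136 (SD, n = 4) in SDHR. Below -3 units the liver arrays held 10 values, all from this probe and ILMN_1241675, while the lowest other liver value was -1.39.

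Resveratrol under alternate-day feeding was compared with EOD, within a set. In heart 1099 probes rose and 1147 fell. In liver 1 probe rose, in muscle 11 rose and 6 fell, and in fat no probe passed in limma, where 123 had an unadjusted p below 0.05. By dose in heart, 2004 rose and 1966 fell in EODHR against EOD, and 31 and 105 in EODLR, or 21 and 22 in EODLR after quantile normalization. The doses differed in heart for 2174 higher and 1715 lower probes at 0.04%, and in liver for 245 higher and 178 lower. In heart the balance turned after quantile normalization, to 1839 higher and 1980 lower; it gave 1991 and 2093 at 0.04% against EOD and 1319 and 1223 for both doses. No filter gave 2139 and 2433 at 0.04%. The liver dose difference passed for 0 probes in the limma fit of the compared groups alone. No probe passed between doses in muscle (1006 at an unadjusted p below 0.05) or fat (234) in limma, but 47 did in muscle without EODHR 6A. The single liver probe was ILMN_1241675, which rose by 3.39 units with an SE of 0.518 and an adjusted p of 0.00165 (limma). Its mean was -2.78 ± 2.23 (SD, n = 3) in EOD, from -4.25 to -0.211, against 0.617 ± 0.107 (SD, n = 5) in EODLR and 0.615 ± 0.0930 (SD, n = 4) in EODHR. The resveratrol groups thus lay at the level of SD18 (0.623) and SD27 (0.624), and the difference rests on EOD 4B and 4C, so that its size is not well defined. After quantile normalization it was 1.83 units. It no longer passed without EOD 4B, at 2.85 units, or without EOD 4C, at 2.66 units, nor in a fit of the compared groups alone. The heart count was 1474 without EOD 4D, and 683 in a fit of the compared groups alone. At 0.01% in heart the count was 704 without EOD 4B, 1 without EOD 4A, 0 without EOD 4C, 81 without EOD 4D, and 65 and 46 without EODLR 5B and 5E. In liver EODLR 5B and 5D lay at 0.352 and 0.411 on the first principal component and the other EODLR arrays at 0.115 or below. The liver dose difference fell to 2 without this pair, a choice made after the data were seen, and to 31 without EODHR 6C, and each other array left out moved it by over 1.5 times. The muscle count ran from 0 without EOD 4B or 4C to 189 without EOD 4A, and was 82 without EOD 4D, 3, 4 and 105 without EODLR 5B, 5C and 5D, 32 without EODHR 6A, and 1 without EODHR 6C or 6D.

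The comparison of SD27 with SD18, planned as one of age, crosses the sets and has no value within a set. It gave 2841 higher and 2899 lower probes in heart, 570 and 634 in liver, 692 and 447 in muscle, and 1341 and 1854 in fat. Without the filter the heart had 2942 higher and 4608 lower probes. In liver the compared groups alone gave 761 higher and 526 lower probes. There 338 passed without SD27 1B and 799 without SD18 1F. In muscle 691 passed without SD27 1C, the compared groups alone gave 601, and quantile normalization gave 553 higher and 643 lower probes. In fat 1915 passed without SD27 1A, and the compared groups alone gave 1202.

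The effects against SD18 were correlated across probes. Those of resveratrol on the standard diet and of alternate-day feeding correlated at 0.940 in heart, 0.694 in liver, 0.784 in muscle and 0.964 in fat, where simulated medians without any effect were 0.612, 0.573, 0.559 and 0.589. The liver value lay within the 95% range of the simulations (0.144 to 0.845) and the muscle value just above it (0.182 to 0.769); in heart the range was 0.332 to 0.832 and in fat -0.0355 to 0.895. The covariances lay above their simulated ranges in every tissue: 0.179 in heart (upper limit 0.00697), 0.0484 in liver (0.0192), 0.0239 in muscle (0.00790) and 0.298 in fat (0.0229). With the SD18 arrays split between the comparisons the correlations were 0.907 in heart, 0.602 in liver, 0.627 in muscle and 0.881 in fat. Every SD18 array lies in the other set, so the split does not remove the crossing of the sets. With SD27 as the shared control, within a set, the correlation was 0.164 in heart, 0.501 in liver, 0.540 in muscle and 0.785 in fat, against simulated medians of 0.670, 0.617, 0.671 and 0.609. The covariance was then 0.0374 in fat, above the simulated 95% range of 0.00107 to 0.0186. In liver it was 0.0158 (0.00123 to 0.0170) and in muscle 0.00722 (0.00221 to 0.0137), both within the range, and in heart 0.00178, just under it (0.00180 to 0.0105). Resveratrol on the standard diet and SD27, both against SD18, correlated at 0.985 in heart, 0.866 in liver, 0.840 in muscle and 0.941 in fat, against simulated medians of 0.532, 0.573, 0.499 and 0.609 and upper limits of 0.810, 0.862, 0.783 and 0.849. With the SD18 arrays split between the comparisons these correlations were 0.952 in heart, 0.755 in liver, 0.672 in muscle and 0.840 in fat.

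Whether resveratrol acted differently by diet was tested as a difference of effects. With SD18 as the control of the standard diet, the effect on the high-calorie diet differed for 5099 probes in heart, 1172 in liver, 998 in muscle and 3237 in fat. With SD27, so that each effect stays within a set, it differed for none in heart in limma (425 at an unadjusted p below 0.05), 22 in liver, 1 in muscle and 283 in fat. The effect under alternate-day feeding differed from that on the standard diet for 5270 probes in heart (2585 higher and 2685 lower, or 4500 and 2880 without the filter), 483 in liver, 1362 in muscle and 4037 in fat with SD18. With SD27 it differed for 314 in heart, 8 in liver, none in muscle (943 at an unadjusted p below 0.05) and none in fat (1352) in limma. The liver value against alternate-day feeding with SD18 was 222 without SD18 1D, 308 without SD18 1F, and 231, 258 and 291 without EOD 4A, 4B and 4C.

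Whether effects differed between heart, liver and muscle was tested over 6273 probes. A z-score unit is the SD of all probe values on an array, so its size in signal may differ between tissues. The fit also used a single spread per probe for these tissues. How far such differences of scale add to the counts was not tested. The effect of the high-calorie diet differed by tissue for 281 probes, that of resveratrol on the high-calorie diet for 60, and that of resveratrol under alternate-day feeding for 909. The effect of alternate-day feeding differed for 3847 probes against SD18 and for 586 against SD27, and that of resveratrol on the standard diet for 4456 and 7. The difference of SD27 from SD18 itself differed by tissue for 3815 probes. Without animal 1F, 1G, 7A or 7C the count for the high-calorie diet was 142, 181, 180 or 187. Without animal 4C that for resveratrol under alternate-day feeding was 479. For resveratrol on the high-calorie diet it was 25, 32, 39 and 23 without animals 7A, 7B, 7C and 7D, 21 without 8E and 33 without 9B.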

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

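The tests on the sets of arrays and on the placing of heart arrays by dose, and the choice of the patterns, came after those results were seen. The bound of the dose test was changed after its own result was seen. The tests of the dose patterns on the dimmest probes, the left-out fat arrays and the splits of the arrays were set before their results.

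The separation of SD18, HC, HCLR and HCHR from the other 6 groups underlies the comparisons of SD27, EOD, SDLR and SDHR with SD18. The z-scores already gave the arrays of a tissue nearly equal SDs, so a difference in SD could not be tested by quantile normalization. That step removes remaining differences in the distribution of values. Resveratrol on the standard diet against SD18 then still gave 6453 probes in heart, 2525 in liver, 2310 in muscle and 4687 in fat. These counts argue against such remaining differences as the sole source of the separation. A batch of hybridization or scanning may add to the separation, since dim probes were called too. Of 1458 probes among the dimmest 30% in every tissue, 49.9% were called in heart for resveratrol on the standard diet against SD18. That share was 1.85% in liver, 9.26% in muscle and 34.4% in fat. For EOD against SD18 it was 35.6% in heart. After quantile normalization the shares for resveratrol were 31.1% in heart, 8.44% in muscle and 21.7% in fat. The directions then turned in fat, from 396 higher and 106 lower to 110 and 206, and in muscle, from 15 and 120 to 77 and 46. Calls among dim probes thus changed with the normalization, in share in heart and fat and in direction in muscle and fat. In muscle the share hardly moved. Whether the distribution of values caused these calls was not tested. In heart 0.0686% were called against SD27 and 0% between HC and SD18. In liver and muscle the share was too low, and in fat the share called between HC and SD18 (8.50%) too high, for this test to decide. A biological difference shared by these groups, such as age at sampling, cannot be told apart from a batch, because 0 of the groups had arrays on both sides in any tissue.

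In heart, 3889 probes differed between 0.04% and 0.01% resveratrol under alternate-day feeding, and the 0.01% array 5A correlated at 0.846 with the 0.04% group and at 0.407 with its own. An exchange of single arrays between the groups, one for one, is argued against, since 0 of the 4 arrays at 0.04% correlated better with the 0.01% group. This test is blind to an exchange of all labels of both groups. A batch of arrays that cuts across the doses may account for part of it, with 9.95% of the dimmest probes called between doses (6.38% after quantile normalization). That share is just under the 10% set for the test to speak for a batch. The dose of resveratrol stays open too: 1 array of 5 lay with the other dose, by 0.439 in correlation, and a wrong label on that array was not tested. Without it the count was 4510.

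In fat, 3686 probes passed between HC with 0.04% resveratrol and HC alone, on 2 arrays each, and 1366 in a fit of the compared groups alone. A batch of arrays may contribute, since 34.6% of the dimmest probes were called (416 higher and 89 lower, or 172 and 206 after quantile normalization). Resveratrol on the standard diet against SD18 in fat, which crosses the sets, gave 34.4% (396 higher and 106 lower). Staying within a set thus did not free this fat comparison of calls among dim probes. A single array was not shown to carry the count, which stayed at 2060 without HCHR 9D, between the bounds set for that test. An effect of the dose stays open, and with 2 arrays per group other splits of the arrays were not run.

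Further differences of effects passed a test of the difference itself. Doses differed for 522 probes on the standard diet and 423 under alternate-day feeding in liver, and on the high-calorie diet for 107 in muscle and 2545 in fat; in the compared groups alone these were 329, 0, 5 and 46 in limma, and 423 became 2 without EODLR 5B and 5D. The resveratrol effect on the high-calorie diet differed from that on the standard diet for 5099 probes in heart, 1172 in liver, 998 in muscle and 3237 in fat, and the effect under alternate-day feeding for 5270, 483, 1362 and 4037; all of these cross the sets. With SD27 as the control they were 0, 22, 1 and 283, and 314, 8, 0 and 0, in limma. Between heart, liver and muscle, 3815 probes differed for SD27 against SD18, 3847 for alternate-day feeding (586 against SD27), 281 for the high-calorie diet, and 4456 (7 against SD27), 909 and 60 for resveratrol on the standard, alternate-day and high-calorie diets.

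Single arrays lay apart from their group on the first principal component in 4 of 26 groups tested, where chance flags about 1 in 20: heart SD18 1D at -0.182, heart EOD 4B at 0.132, muscle SDLR 2B at 0.122 and muscle EODLR 5D at 0.256. Among 32 liver groups of the named probes, 3 arrays lay apart: HC 7C at 3.85 and HCLR 8E at 3.06 for ILMN_1243128, and SDHR 3C at -0.00012 for ILMN_1241675, whose other 3 SDHR arrays lay between -3.73 and -3.66.

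Other splits of the same arrays, at most 100 drawn, were refitted for each comparison of groups of at least 3 arrays. The share of splits with as many probes as the real one, itself included, was set against 0.05. No correction was made for the number of comparisons. Comparisons of SD27, EOD, SDLR and SDHR with SD18, and resveratrol effects by diet, cross the sets. There the real labels follow a separation already seen, so a high rank was fixed beforehand and does not speak for the diet. In heart, the share was under 0.05 for 5740 for SD27 against SD18 (highest other 4768) and 5780 for alternate-day feeding (highest other 2936). So it was for 27 for the high-calorie diet (highest other 5), which ran from 7 to 39 with 1 array left out. The same held for 6411 for resveratrol on the standard diet (highest other 4520), 3889 for the dose difference under alternate-day feeding (highest other 3476) and 5099 for the resveratrol effect by high-calorie diet (highest other 3074). It also held for 5270 for the resveratrol effect by alternate-day feeding (highest other 2787). The share was under 0.05 for 2246 for resveratrol under alternate-day feeding too, although 2 of 100 splits, the real among them, gave as many and the highest 2778. Chance was not excluded for 518 for alternate-day feeding against SD27, where 2 of 35 splits gave as many and the highest other 765. Counts of 0 were matched by every split (100 of 100), with a highest other of 30 for resveratrol on the high-calorie diet, 8 for the dose difference on the standard diet, 5 for the dose difference on the high-calorie diet and 24 for resveratrol on the standard diet against SD27.

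In liver, the share was under 0.05 for 1204 for SD27 against SD18 (highest other 132) and 1914 for alternate-day feeding (highest other 1024). So it was for 499 for the high-calorie diet (highest other 1). The same held for 2341 for resveratrol on the standard diet (highest other 493), 39 for resveratrol on the high-calorie diet (highest other 15) and 522 for the dose difference on the standard diet (highest other 181). It also held for 1172 for the resveratrol effect by high-calorie diet (highest other 38) and 483 for the resveratrol effect by alternate-day feeding (highest other 388). The share was just under 0.05 for 423 for the dose difference under alternate-day feeding, where 4 of 100 splits, the real among them, gave as many and the highest 876. That count ran from 31 to 821 with 1 array left out, so it is weakly supported. The same applies to 39 for resveratrol on the high-calorie diet, which ran from 1 to 76. Chance was not excluded for 1 for resveratrol under alternate-day feeding, where 26 of 100 splits gave as many and the highest other 1846. Chance was not excluded for 16 for resveratrol on the standard diet against SD27, where 5 of 100 splits gave as many and the highest other 367. Counts of 0 were matched by every split (35 of 35), with a highest other of 1 for the dose difference on the high-calorie diet. For alternate-day feeding against SD27 10 splits are too few for a share under 0.05; the real count of 1368 was the largest (1 split), with a highest other of 0.

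In muscle, the share was under 0.05 for 1139 for SD27 against SD18 (highest other 147) and 1898 for alternate-day feeding (highest other 891). So it was for 227 for the high-calorie diet, although another split gave 218 and not every split was run. The same held for 2168 for resveratrol on the standard diet (highest other 794), 107 for the dose difference on the high-calorie diet (highest other 50) and 998 for the resveratrol effect by high-calorie diet (highest other 110). It also held for 1362 for the resveratrol effect by alternate-day feeding (highest other 1) and 59 for alternate-day feeding against SD27 (highest other 9). The share was under 0.05 for 249 for resveratrol on the high-calorie diet too, although 3 of 100 splits, the real among them, gave as many and the highest 572. With 1 array left out, 227 ran from 92 to 356, 107 from 2 to 233 and 249 from 47 to 503, so these counts are weakly supported. Chance was not excluded for 17 for resveratrol under alternate-day feeding, where 6 of 100 splits gave as many and the highest other 510. Chance was not excluded for 1 for resveratrol on the standard diet against SD27, where 23 of 100 splits gave as many and the highest other 711. Counts of 0 were matched by every split (100 of 100), with a highest other of 344 for the dose difference on the standard diet and 245 for the dose difference under alternate-day feeding.

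For differences between these tissues, the share was under 0.05 for 3815 for SD27 against SD18 (highest other 3414). So it was for 3847 for alternate-day feeding (highest other 1891) and 281 for the high-calorie diet (highest other 161). The same held for 4456 for resveratrol on the standard diet (highest other 2187), 909 for resveratrol under alternate-day feeding (highest other 763) and 60 for resveratrol on the high-calorie diet (highest other 18). For resveratrol under alternate-day feeding some splits called several times the real count (1846 against 1 in liver, 510 against 17 in muscle). Those splits deal the EOD, EODLR and EODHR arrays together. Differences between the doses and structure of the arrays outside the groups cannot be told apart there. In liver, EODLR 5B and 5D stood apart on the first principal component, at 0.352 and 0.411 against 0.0379 to 0.115 for the other 3 EODLR arrays. Whether the splits with the most calls part this pair from the rest was not tested.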

How the results depend on the processing

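Alternatives with SD27 for the differences of effects by diet, the tissue differences and the correlations, and the one without EODLR 5B and 5D, were chosen after the data were seen. Of 58 counts, quantile normalization moved 6 by over 1.5 times and no filter moved 13. The compared groups alone moved 19 of 52, and SD27 as the control moved 22 of 23. The alternative of the mean over a gene's probes and those of the gene lists were not run, for want of gene names. Signal over background is not known for these z-scores. Except where stated, the cause was not tested.

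With SD27 as the control, alternate-day feeding gave 518 probes in heart, 59 in muscle and 293 in fat, where SD18 had given 5780, 1898 and 4793; liver, with 1368 against 1914, stayed within 1.5 times. Resveratrol on the standard diet gave 0 in heart, 16 in liver, 1 in muscle and 236 in fat. The high-calorie diet, which then crosses the sets, gave 5435 in heart, 2203 in liver, 1988 in muscle and 4265 in fat. The resveratrol effect on the high-calorie against the standard diet differed for 0, 22, 1 and 283 probes in heart, liver, muscle and fat, and that under alternate-day feeding for 314, 8, 0 and 0. By tissue, 586 probes differed for alternate-day feeding, 3797 for the high-calorie diet and 7 for resveratrol on the standard diet. The correlation of resveratrol on the standard diet with alternate-day feeding was 0.164 in heart, 0.501 in liver and 0.540 in muscle. With HC arrays split, that of resveratrol on the high-calorie diet with the diet was 0.129 in heart, turned from -0.148, -0.431 in liver and -0.254 in muscle, and -0.425 in fat against -0.565; the split removes the shared arrays by construction.

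The fit of the compared groups alone, which has fewer arrays for the spread, gave these counts. For resveratrol under alternate-day feeding it gave 683 in heart, 0 in liver and 1 in muscle; at 0.01% 0 in heart and 0 in liver, and at 0.04% 6 in liver. For resveratrol on the high-calorie diet it gave 3 in liver, 155 in muscle and 28 in fat; at 0.01% in fat 0, and at 0.04% in fat 1366. Dose differences were 329 on the standard diet in liver, 0 in liver and 1 in muscle under alternate-day feeding, and 5 in muscle and 46 in fat on the high-calorie diet. SD27 against SD18 gave 601 in muscle and 1202 in fat, and the high-calorie diet 893 in fat.

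Without the filter, resveratrol at 0.01% under alternate-day feeding gave 86 in heart and both doses 53 in muscle. The dose difference was 1079 on the standard diet in liver, and 71 in muscle and 4393 (2549 higher, 1844 lower) in fat on the high-calorie diet. Resveratrol on the high-calorie diet in fat gave 2981, 1 at 0.01% and 5989 (3310 higher, 2679 lower) at 0.04%; these fat balances turn from an excess of falls. By tissue, 5874 probes differed for SD27 against SD18, 6557 for alternate-day feeding, 425 for the high-calorie diet, 7267 for resveratrol on the standard diet and 102 for it on the high-calorie diet. Quantile normalization gave 1 for the heart dose difference on the high-calorie diet. At 0.01% under alternate-day feeding it gave 43 in heart and 24 in liver, and for both doses 2 in muscle. Its dose difference on the high-calorie diet was 67 in muscle and 1295 in fat. Without EODLR 5B and 5D the liver dose difference under alternate-day feeding was 2 and the 0.01% count 4.

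With 1 array left out in turn, counts ranged as follows. A group left with 1 fat array was assumed to vary like the others. High-calorie diet: 7 to 39 in heart, 268 to 456 in liver, 92 to 356 in muscle and 1213 to 2602 in fat. Resveratrol on it: 0 to 1 in heart, 1 to 76 in liver, 47 to 503 in muscle and 256 to 2092 in fat. At 0.01% this was 0 to 2 in muscle and 0 to 273 in fat, and at 0.04% 470 to 1019 in muscle and 2060 to 3341 in fat. Its dose difference was 0 to 33 in heart, 2 to 233 in muscle and 815 to 2378 in fat. Resveratrol under alternate-day feeding: 1474 to 2467 in heart, 0 to 2 in liver and 0 to 189 in muscle. At 0.01% this was 0 to 704 in heart and 0 to 115 in liver, and at 0.04% 0 to 3 in liver. Its dose difference was 31 to 821 in liver and 0 to 47 in muscle. The dose difference on the standard diet was 0 to 3 in heart, 255 to 480 in liver and 0 to 1 in fat. SD27 against SD18: 338 to 1029 in liver, 691 to 1155 in muscle and 1915 to 2652 in fat. Alternate-day feeding against SD18: 1131 to 1812 in liver. The resveratrol effect under alternate-day feeding against the standard diet: 222 to 586 in liver. By tissue, without 1 animal: 142 to 260 for the high-calorie diet, 479 to 1052 for resveratrol under alternate-day feeding and 21 to 65 for it on the high-calorie diet. The fall of ILMN_1234449 on the high-calorie diet ran from -4.29 to -4.13 units and the rise of ILMN_2617625 from 2.71 to 3.10; against SD27 they were -2.76 and 2.36. ILMN_1241675 under alternate-day feeding with resveratrol rose by 2.66 to 4.68 units with 1 array left out and by 1.83 after quantile normalization, and no longer passed in the compared groups alone or without EOD 4B or 4C. The fall of ILMN_1243128 with resveratrol on the standard diet ran from -3.84 to -3.75, and was -2.74 after quantile normalization.

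Arrays of the same animal code in different tissues deviated together at most weakly, and the rule set for pairing was not met. Their deviations from the group means correlated at medians of 0.0790 for heart and liver, 0.0190 for heart and muscle and 0.0538 for liver and muscle. The correlation was above 0.1 for 12 of 36, 16 of 41 and 12 of 39 codes. Of the same 36, 41 and 39 codes, 6, 4 and 6 correlated best with their own code. These numbers were not set against a chance value, so a weak pairing of tissues by animal is not excluded. With the animal code as a random block (estimated correlation 0.0361) no tissue difference moved by over 1.5 times. It gave 3889 probes for SD27 against SD18, 3891 for alternate-day feeding, 314 for the high-calorie diet, and 4498, 991 and 67 for resveratrol on the standard, alternate-day and high-calorie diets.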

Other observations

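These values were picked out after they were seen, and no explanation of them was tested. On the high-calorie diet the effects of 0.04% resveratrol in muscle and in fat correlated at -0.247 across 7221 probes, which are not independent replicates. Of the probes that passed in both tissues, 284 went in opposite directions, against 154 for independent lists. The fat groups had 2 arrays each. For the high-calorie diet itself the effects correlated at 0.243 in muscle and fat, 0.199 in liver and muscle, and 0.159 in heart and muscle. For alternate-day feeding against SD27 they correlated at 0.283 in liver and muscle, 0.273 in liver and fat, and 0.198 in heart and liver.

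A pair of liver probes took values far below all others. ILMN_1243128 lay between -3.89 and -3.45 in SDHR 3A, 3B, 3C and 3E and in EOD 4A, and its next lowest value was 2.44. ILMN_1241675 lay between -4.25 and -3.66 in SDHR 3A, 3B and 3E and in EOD 4B and 4C, and its next lowest value was -0.211. No heart, muscle or fat array held a value below -3; the lowest were -1.36, -1.32 and -1.41.

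In liver, resveratrol at 0.04% on the standard diet gave 214 higher and 76 lower probes against SD27, while 0.01% gave none in limma (676 at an unadjusted p below 0.05). The doses themselves differed for 522 probes.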
